A study of Homo sapiens with 11 samples.

How the data were processed

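ChIP-seq peak lists of 10 libraries were analysed, 2 for each of 5 groups: MYRF in CFPAC1, MYRF in HPAF2, FOS in a CFPAC1 control clone, H3K27ac in the CFPAC1 control clone and H3K27ac in a CFPAC1 clone carrying Cas9 and a guide against MYRF. The series also lists 1 HPAF2 input sample without a peak list, which was not analysed here. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 min, and each precipitation used 10 µg of antibody. Per the labels, the MYRF antibody was made by the submitters and was used on the original lines, whereas FOS and H3K27ac were mapped in clones. Control and knockout differ in clone as well as in MYRF.

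Per the submitters' processing notes, the authors used Trimmomatic 0.38, Bowtie2 2.2.6, SAMtools and MACS2 2.1.0.20150731, with the human assembly GRCh38 (hg38). In the deposited lists each peak carries the authors' fold enrichment at the summit (a ratio over the local background estimate), the -log10 p, the -log10 q and a score, the whole part of the -log10 q times 10. The lowest -log10 q of each deposited list lay just over 1.30. The lists have no header and no read counts, so depth is unknown, and no limit or interval that needs it is given. Fold enrichment is scaled to each library's own background. The labels do not say which input or control was used to call the CFPAC1 peaks, so what the CFPAC1 folds are relative to is not known. It was therefore used only to describe, rank and stratify peaks within a list, and lists were compared by presence, absence and covered length. No interval with an equal fold occurred in both replicates of a group, so no list was a copy of its partner.

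Peaks overlapping by at least 1 bp counted as shared, and overlapping peaks of both replicates were merged into a reproducible set. H3K27ac peaks of the 4 libraries were merged into regions, scored as present or absent in each library. A region present in both control and neither knockout library was called lost, and the opposite gained. Odds ratios between region classes came from two-sided Fisher's exact tests, with 95% intervals on the log scale. Loss and gain were tested by Mantel-Haenszel odds ratios over 10 strata of H3K27ac fold enrichment, with exact conditional tests, because weak peaks drop out of lists more often. Around each transcription factor summit, base pairs covered by H3K27ac peaks were counted in a window of 2000 bp. Shares carry Wilson 95% intervals, which describe counting over peaks and not variation between cultures. Regions of 1 genome are not independent replicates of a knockout, so p-values from them speak for these libraries. Groups of 2 allow no outlier test.

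The annotation was the RefSeq gene table for GRCh38 with 20037 protein-coding genes, without strand or transcripts. Distances were taken to the nearer end of a gene, within 1 kb for gene ends and 50 kb for assignment, in place of transcription start sites. All 408 genes of the 16 lists were found by symbol. Lists were tested by Fisher's exact test against 12436 genes with an H3K27ac peak within 1 kb of an end in both control libraries, with Benjamini-Hochberg adjustment over the 16 lists within a peak set and an adjusted p threshold of 0.05. HPAF2 used the same background, since no HPAF2 H3K27ac list was analysed here. The lists were ER chaperones and folding enzymes, unfolded protein response regulators, ER-associated degradation, N-glycosylation, O-glycosylation, ER translocation and signal peptide processing, ER-to-Golgi transport, mucins and other large epithelial glycoproteins, the classical and basal-like pancreatic cancer programs, epithelial and pancreatic transcription factors, AP-1 and related factors, myelin and oligodendrocyte genes, mesenchymal genes, acinar genes and cytosolic ribosomal proteins.

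Named genes followed a rule set before the data were examined. It took MYRF and up to 6 genes per list with a MYRF peak in both lines, the 12 genes nearest the shared MYRF peaks of highest within-list percentile, the 10 lost, 10 gained and 10 lost MYRF regions of highest percentile in replicate 1 of the clone that had them, and up to 6 members of each passing list. Some items that the rule selects are withheld and not reported here. Genes named outside it are said to be chosen after their values were seen. The lists, tests and alternatives of the main comparisons were fixed before the data were examined. The counts of lost against gained MYRF sites, the coverage comparison, list tests on regions or gene spans and those on mixed groupings were added afterwards. Alternatives covered the overlap rule, a -log10 q of at least 10, the region definition, the assignment distance, the background and leaving out each replicate.

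Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlaps and merged regions were checked against bedtools 2.31.1 and differed in 0 cases. On simulated data with the real strata, the Mantel-Haenszel estimate had medians of 0.50, 1.01, 2.06 and 3.99 for true odds ratios of 0.5, 1, 2 and 4, with 46, 2, 50 and 50 calls in 50 runs. Loss was drawn there for each region independently from the rate of its stratum, so these runs check the code only. They do not show that the test is calibrated on the real regions, where mixed groupings of the libraries gave MYRF values from 0.23 to 0.38. Simulated lists of 26 genes were called in 5.5%, 88.5% and 100% of 200 runs at true odds ratios of 1, 4 and 8. These shares hold for a list of that size tested alone, without the adjustment over all lists that the reported calls use. They give neither the false call rate of the adjusted tests nor their power for the ER lists, which have other sizes. The motif test and the test on all annotated transcript starts were not run, because neither a genome sequence nor transcript starts were used here.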

Results

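Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 3 targets in CFPAC1 and HPAF2, human cell lines derived from pancreatic ductal adenocarcinoma. MYRF is a transcription factor best known for switching on myelin genes in oligodendrocytes, and it is made as a membrane protein of the endoplasmic reticulum (ER) that releases its DNA-binding part by self-cleavage. FOS is a subunit of the AP-1 transcription factor, and H3K27ac, the acetylation of histone H3 at lysine 27, marks active promoters and enhancers. The study title ties MYRF to ER homeostasis, so the comparisons ask where MYRF sat in the genome, near which genes, how its sites related to FOS sites, and how H3K27ac differed between a control clone and a MYRF knockout clone of CFPAC1. Each of the 5 groups with peak lists held 2 libraries. CFPAC1 MYRF replicates 1 and 2 had 4743 and 4041 peaks, HPAF2 MYRF 3702 and 4326, and FOS in the CFPAC1 control clone 29087 and 36349. H3K27ac had 116466 and 109352 peaks in the control clone and 107586 and 110498 in the knockout clone. The lists carry no read counts, so the sequencing depth of every library is unknown. The labels do not say whether replicates were separate cultures, so the spread between them, and every p-value below, may cover technical variation alone.

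The strongest MYRF peaks recurred in both libraries of a line and in both lines. The peak with the best joint rank lay inside GRAMD1B, which encodes a sterol carrier of the ER membrane, at chromosome 11, positions 123587901 to 123588753 (GRCh38, counted from 1). Its fold enrichment over the background estimate, for which the labels name no control in CFPAC1, was 50.7 and 51.2 in the CFPAC1 replicates and 93.2 and 100.014 in the HPAF2 replicates. Next came a peak inside ANXA4, a calcium-dependent phospholipid-binding protein (chromosome 2, 69780904 to 69782101), with 66.7 and 68.6 in CFPAC1 and 51.0 and 56.1 in HPAF2. The third lay 890 bp from an end of TM4SF4, a transmembrane protein (chromosome 3, 149473125 to 149474276), at 44.3 and 44.7 in CFPAC1 and 53.7 and 53.2 in HPAF2. Other nearest genes of the top 12, in order of rank, included ATXN10, ANKRD46, HORMAD2, the semaphorin receptor gene PLXNB2, the mitotic kinase gene NEK6, the sulfatase gene ARSI, the cyclic GMP phosphodiesterase gene PDE9A and the granule release gene UNC13D. Among these, the HORMAD2 peak had the highest CFPAC1 values, 80.9 and 81.3, and the PDE9A peak the highest HPAF2 values, 81.0 and 86.8.

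Within CFPAC1, 59.7% of replicate 1 MYRF peaks were overlapped by a replicate 2 peak (95% Wilson interval 58.3 to 61.1). Within HPAF2 the share was 78.5% (77.2 to 79.8). Recovery followed peak strength. In the top quintile of replicate 1 by fold enrichment, 97.5% of CFPAC1 peaks and 99.5% of HPAF2 peaks were found again, against 37.1% and 59.7% in the lowest quintile. Peaks found in both libraries numbered 2793 in CFPAC1, 2883 in HPAF2 and 26211 for FOS, and these reproducible sets were used from here on. Between lines, 1284 of the 2793 CFPAC1 peaks, or 46.0% (44.1 to 47.8), were overlapped by an HPAF2 peak, and 44.4% (42.6 to 46.2) of HPAF2 peaks by a CFPAC1 peak. The share found in HPAF2 was 78.0% in the top quintile of CFPAC1 peaks and 29.4% in the lowest quintile. Among 68770 H3K27ac regions present in both control libraries, those with a CFPAC1 MYRF peak held an HPAF2 MYRF peak in 51.3% of cases and the rest in 1.60%, an odds ratio of 64.8 (95% interval 58.7 to 71.5, Fisher's exact test). The odds ratio was 138 with a stricter peak threshold and 109 over the union of all H3K27ac regions. Peaks found in CFPAC1 alone numbered 1509 and in HPAF2 alone 1604, and the lines were grown in different media, which the design does not separate from the line.

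MYRF peaks lay mostly away from gene ends, though less so than FOS peaks. Of CFPAC1 peaks, 10.2% (9.14 to 11.4) lay within 1 kb of either end of a protein-coding gene, against 7.16% (6.86 to 7.48) of FOS peaks (odds ratio 1.47, 1.29 to 1.68, Fisher's exact p = 2.9e-08). The HPAF2 share was 8.71% (odds ratio against FOS 1.24, 1.08 to 1.42, Fisher's exact p = 0.0033). Inside the span of a protein-coding gene lay 52.8% of CFPAC1, 46.4% of HPAF2 and 51.2% of FOS peaks. For scale, 15.7% and 16.7% of H3K27ac peaks in the control libraries lay within 1 kb of a gene end. Because the annotation carries no strand, gene starts and gene ends were not told apart.

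Each peak was assigned to the protein-coding gene with the nearest end within 50 kb, and 16 gene lists chosen before the data were examined were tested by Fisher's exact test against 12436 genes with an acetylated end in both control libraries. The lists that passed for MYRF were mostly not particular to it. In CFPAC1, 4 lists held more genes with a MYRF peak, as a share, than the other background genes. They were mucins and other large epithelial glycoproteins (10 of 26 genes, odds ratio 5.88, exact test, adjusted p = 0.0014), the basal-like pancreatic cancer program (7 of 15, 8.22, adjusted p = 0.0020), AP-1 and related factors (6 of 12, 9.39, adjusted p = 0.0024) and epithelial and pancreatic transcription factors (7 of 22, 4.38, adjusted p = 0.014), where the background rate was near 9.67%. In HPAF2, 5 lists passed: the glycoproteins (12 of 26, odds ratio 8.59, exact test, adjusted p = 1.5e-05), the epithelial factors (8 of 22, 5.71, adjusted p = 0.0038), myelin and oligodendrocyte genes (4 of 7, 13.3, adjusted p = 0.010), AP-1 factors (5 of 12, 7.12, adjusted p = 0.012) and the basal-like program (5 of 15, 4.98, adjusted p = 0.028). The myelin list stood at 3 of 7 genes in CFPAC1 (exact test, adjusted p = 0.075). All 4 CFPAC1 lists also passed for FOS peaks, at odds ratios of 5.94 (glycoproteins), 4.31 (basal-like program), 11.9 (AP-1 factors) and 4.86 (epithelial factors). H3K27ac regions found only in control replicate 2 and knockout replicate 2 form a grouping unrelated to the knockout. They also passed for glycoproteins (7 of 26, exact test, adjusted p = 0.025), AP-1 factors (5 of 12, 0.024) and epithelial factors (6 of 22, 0.031). Most lists had too few genes hit in a single line for an exact test between lines to decide. MYRF was assigned to 678 of the same genes in both lines, out of 1202 in CFPAC1 and 1138 in HPAF2, where independent draws would give 110.

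Among the tested glycoprotein genes, the shared peak of best joint rank lay inside CDH1, which encodes E-cadherin (7.32 and 11.4 in CFPAC1, 10.3 and 11.1 in HPAF2). Next came a peak 133 bp from an end of MET, the hepatocyte growth factor receptor gene (8.52 and 10.5, 9.35 and 7.62). CEACAM6, an adhesion molecule of epithelial cells, and ITGA3, an integrin chain, also had shared peaks. ITGA6 and LAMA5 had CFPAC1 peaks high in the list, and MUC1, a transmembrane mucin, and ITGA2 had HPAF2 peaks. From the basal-like program, shared peaks lay 177 bp from FAM83A (13.3 and 12.6 in CFPAC1, 19.3 and 21.3 in HPAF2) and near the keratin gene KRT7, the calcium-binding protein gene S100A2, the adhesion gene TNS4 and FGFBP1, a carrier of fibroblast growth factors. The FGFBP1 peak ranked high within the CFPAC1 lists (16.7 and 20.2, percentile 95.7 in the replicate where it was lower) and near the bottom of the HPAF2 lists (2.74 and 3.68, percentile 0.58). Of the epithelial factors, the ETS factor gene ELF3 had the strongest peak (chromosome 1, 202018351 to 202019284) with 22.1 and 22.7 in CFPAC1 and 27.3 and 30.0 in HPAF2, followed by HNF4G, FOXA3 and EHF. FOS itself had a shared MYRF peak 11866 bp from its end (15.5 and 12.4 in CFPAC1, 11.2 and 13.4 in HPAF2), as did BATF and FOSL2. The myelin list was represented by MAG, the galactolipid synthesis gene UGT8 and the myelin basic protein gene MBP in both lines, and by GALC in HPAF2. The mesenchymal list had 0 of 11 genes with a MYRF peak in each line (exact test, unadjusted p = 0.62 in CFPAC1 and 0.61 in HPAF2) and the acinar list 0 of 2. These lists are too short for such counts to show avoidance.

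Lists of the ER protein machinery did not pass in either line. In CFPAC1 and HPAF2 respectively, genes with a MYRF peak numbered 2 and 3 of 32 ER chaperones and folding enzymes, 1 and 3 of 17 unfolded protein response regulators, 1 and 1 of 19 ER-associated degradation genes, 3 and 2 of 38 N-glycosylation genes, 2 and 3 of 24 translocation and signal peptide genes and 6 and 3 of 37 ER-to-Golgi transport genes. The lowest adjusted p of these exact tests was 0.39, for the unfolded protein response in HPAF2. Odds ratios lay on both sides of 1 with wide intervals. In HPAF2 the unfolded protein response had 2.13 (0.61 to 7.42) and N-glycosylation 0.55 (0.13 to 2.29). In CFPAC1 ER-to-Golgi transport had 1.81 (0.75 to 4.35) and chaperones 0.62 (0.15 to 2.61). These counts therefore do not show that an association is absent. O-glycosylation had 3 and 5 of 19 genes (exact test, adjusted p = 0.84 and 0.067), the classical pancreatic cancer program 2 and 3 of 10 (0.57 and 0.13), and cytosolic ribosomal proteins 5 and 7 of 50 (1 and 0.39). Single ER genes nonetheless carried strong shared peaks. ERN2, the epithelial ER stress sensor IRE1 beta, had a peak inside the gene (chromosome 16, 23711732 to 23712160) with 12.5 and 11.6 in CFPAC1 and 29.8 and 31.0 in HPAF2. AGR3, a protein disulfide isomerase, had 31.4 and 34.1 in CFPAC1 and 14.5 and 19.8 in HPAF2, 7147 bp from its end. SSR2, a subunit of the translocon-associated complex, had 20.8 and 21.1, and 15.2 and 13.8, 333 bp from its end. Shared peaks of lower joint rank, which follows the line where a peak ranks lower, lay near further ER genes. These were SEC11A, the catalytic part of signal peptidase, the degradation ligase gene SYVN1 and the cargo receptor genes TMED10 and MCFD2. The oligosaccharyltransferase gene DAD1, DPAGT1, which starts N-glycan assembly, and the disulfide isomerase gene TXNDC11 were others. Some were strong in a single line, as MCFD2 in CFPAC1 (21.7 and 17.3) and TMED10 (26.1 and 27.8) and DAD1 (30.8 and 41.3) in HPAF2. The O-glycosylation genes B3GNT3, GALNT10 and ST6GALNAC1, the classical program genes KRT20 and CDH17 and the ribosomal genes RPS14 and RPL37 had shared peaks as well. AGR3, KRT20 and CDH17 were outside the tested background.

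**Figure D1:**
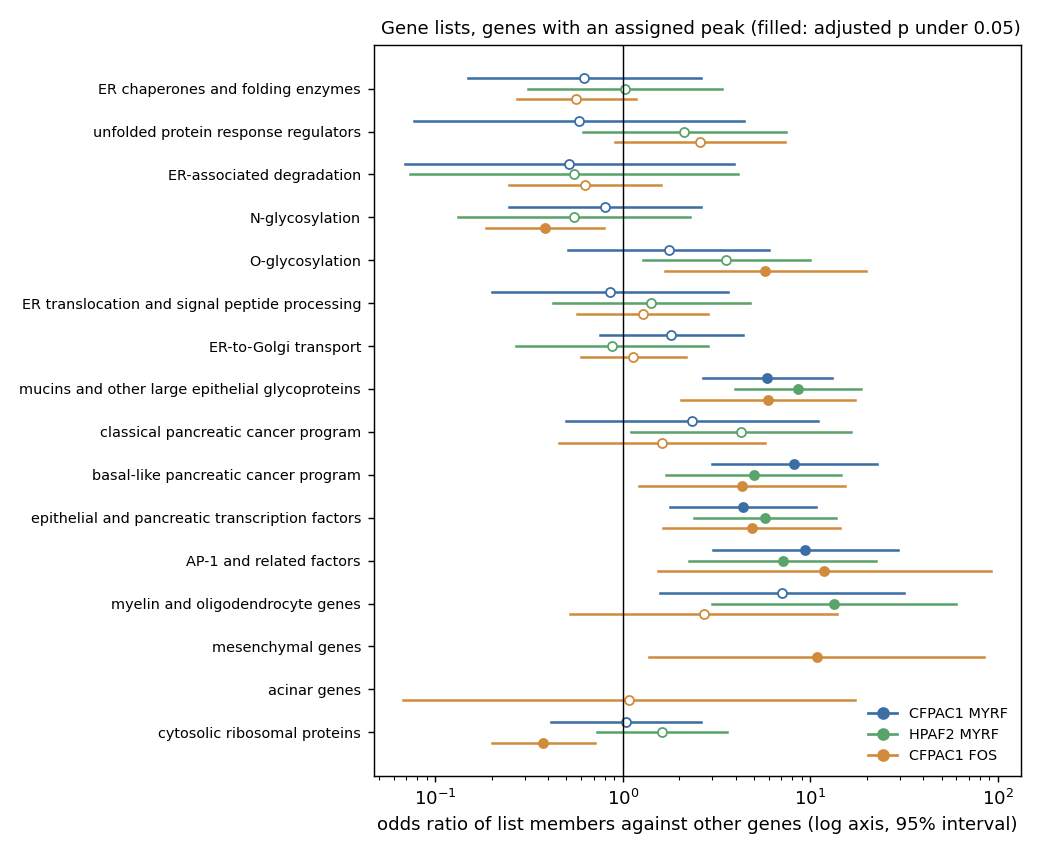
Odds ratio (log axis) of genes with an assigned peak for 16 gene lists, list members against other genes, for CFPAC1 MYRF, HPAF2 MYRF and CFPAC1 FOS. Lines are 95% intervals, filled points have an adjusted p under 0.05, and lists with 0 members hit or no interval have no point; the 6 lists of ER and N-glycosylation machinery have open points for MYRF in both lines.

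The lists that passed for MYRF depended on the settings. In CFPAC1, only the glycoproteins and the basal-like program remained with a stricter peak threshold (exact test, adjusted p = 0.0064 and 0.0056) and with H3K27ac regions rather than genes as units (0.0028 and 0.0078). No list passed with assignment within 5 kb, where the glycoproteins stood at an adjusted p of 0.051 (exact test), and the myelin list passed without replicate 1 (0.027). The glycoprotein odds ratio in CFPAC1 was 19.1 without replicate 2 (20 of 26 genes) and 2.92 with regions as units, and that of AP-1 factors was 5.69 without replicate 2. In HPAF2, no list passed with the stricter threshold, where the glycoproteins stood at 0.078 (exact test, adjusted p), and the glycoproteins passed under all other settings. Within 5 kb the epithelial factors also passed, together with 2 lists that had not passed before, the classical program (exact test, adjusted p = 0.020) and ribosomal proteins (0.012), while AP-1 factors (0.19), the basal-like program (0.24) and myelin genes (0.37) dropped out. With regions as units AP-1 factors (exact test, adjusted p = 0.030) and the classical program (0.047) passed, and epithelial factors (0.057), the basal-like program (0.083) and myelin genes (odds ratio 1.78, 0.58) did not. Against all protein-coding genes the classical program passed (exact test, adjusted p = 0.015) and myelin genes did not (0.097). The myelin call in HPAF2 thus held with gene spans (exact test, adjusted p = 0.017) and without either replicate (odds ratio 8.67 without replicate 1), and ended under the other 4 settings. In HPAF2, O-glycosylation passed with gene spans (exact test, adjusted p = 0.033), ribosomal proteins passed without replicate 1 (0.017), and the basal-like program ended without replicate 2 (0.079).

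FOS peaks coincided with most CFPAC1 MYRF peaks. They overlapped 64.9% (63.1 to 66.6) of CFPAC1 MYRF peaks and 73.5% (71.0 to 75.9) of those also found in HPAF2, against 57.5% (55.0 to 60.0) of those found in CFPAC1 alone. In the other direction, 6.80% (6.50 to 7.11) of FOS peaks had a MYRF peak. Shared sites included those of ELF3, KRT20, TM4SF4, HORMAD2, BATF and CDH1, while the strongest peaks of GRAMD1B, ANXA4, PLXNB2, PDE9A, AGR3, SSR2 and ERN2 were overlapped by no FOS peak. Beside the GRAMD1B peak, however, both FOS libraries had a weak peak (3.26 and 3.10, positions 123587269 to 123587539 and 123587190 to 123587423). Both lay within the H3K27ac region of the control clone there. Among H3K27ac regions of both control libraries, 78.5% of those with MYRF and 27.6% of those without had FOS (odds ratio 9.56, 8.69 to 10.5, Fisher's exact test). Within deciles of H3K27ac strength the odds ratio was 5.89 (5.33 to 6.50), and with summits within 200 bp it was 4.47 (4.12 to 4.85). MYRF was mapped in the original line and FOS in a control clone, so cell source differed along with the target.

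FOS peaks were near 48.1% of background genes, and 8 lists departed from that rate. They were assigned to 22 of 26 glycoprotein genes (exact test, adjusted p = 0.0035), 16 of 19 O-glycosylation genes (0.0080), 18 of 22 epithelial factors (0.0080), 11 of 12 AP-1 factors (0.0081), 10 of 11 mesenchymal genes (0.013) and 12 of 15 basal-like genes (0.036). N-glycosylation, with 10 of 38 genes (odds ratio 0.38, exact test, adjusted p = 0.019), and ribosomal proteins, with 13 of 50 (0.38, adjusted p = 0.0080), had fewer genes than the background. In the lists with more genes than the background, the strongest FOS peaks lay near FGFBP1 (32.5 and 31.5), near VIM, the intermediate filament of mesenchymal cells (25.02 and 24.7), and near the epithelial factor gene KLF4 (20.9 and 21.9). Others lay near FOSL2, ITGA3, MUC5AC, a secreted mucin, TNS4, GALNT5, ZEB1, a repressor of epithelial genes, and FN1, the fibronectin gene. Among N-glycosylation genes, DAD1 had the strongest FOS peak (20.4 and 22.5), and among ribosomal genes RPL3 (16.2 and 16.1). Not passing were chaperones (11 of 32, exact test, adjusted p = 0.25), the unfolded protein response (12 of 17, 0.16), ER-associated degradation (7 of 19, 0.49), translocation (13 of 24, 0.78), ER-to-Golgi transport (19 of 37, 0.79), the classical program (6 of 10, 0.66), myelin genes (5 of 7, 0.40) and acinar genes (1 of 2, 1). Of the 8 passing lists, 4 passed with assignment within 5 kb, 4 against all protein-coding genes, 5 with the stricter threshold and 3 with regions as units. Mesenchymal genes ended without FOS replicate 1 (exact test, adjusted p = 0.059), where the basal-like odds ratio was 10.6 (4.31 with both), and N-glycosylation (0.10) and the basal-like program (0.080) ended without replicate 2.

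The MYRF gene itself (chromosome 11, 61752636 to 61788518) carried a FOS peak in both libraries, at 13.9 and 14.7. MYRF peaks at the same place were called in both HPAF2 libraries (4.51 and 5.22) and in CFPAC1 replicate 1 (4.06, positions 61756585 to 61756844), but not in CFPAC1 replicate 2. All 4 H3K27ac libraries had peaks from its lower-coordinate end onwards, the knockout ones included, and H3K27ac does not check whether the knockout removed the protein.

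Most MYRF sites lay in acetylated chromatin, in the control clone and in the knockout clone alike. H3K27ac peaks overlapped 84.2% (82.8 to 85.5) and 82.6% (81.2 to 84.0) of MYRF peaks in the control libraries and 80.3% (78.8 to 81.8) and 81.6% (80.1 to 83.0) in the knockout libraries. For FOS peaks the shares were 79.7% and 73.2% in control and 73.6% and 75.7% in knockout. Shared MYRF peaks near ELF3, KRT20, TM4SF4, ATXN10, HORMAD2, SEC11A and DAD1 had H3K27ac in all 4 libraries.

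Most regions acetylated in both control libraries kept a peak in the knockout clone. Of 134465 merged H3K27ac regions, 68770 were present in both control libraries and 54063 in all 4, while 4726 were in both control and neither knockout library (lost) and 2287 in both knockout and neither control library (gained). The balance turned without either knockout library, with 8713 lost and 13296 gained without replicate 1 and 10720 and 12446 without replicate 2, and without control replicates 1 and 2 in turn it was 15180 against 5700 and 18729 against 4372. Regrouping the libraries in the other 2 ways gave 2680 and 2281 regions for 1 grouping and 4733 and 2591 for the other, so the lost count was no higher than the largest count from a mixed grouping. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.33. Ranked by fold enrichment in control replicate 1 alone, the top lost regions with a gene end within 50 kb lay near CDH2, the N-cadherin gene (10.0 and 5.51 in the control libraries, chromosome 18, 28203853 to 28204265), inside ENPP7, an intestinal sphingomyelinase gene (9.92 and 6.46), inside EVI2B (9.36 and 7.56) and inside TLE5, a transcriptional corepressor gene (9.20 and 5.54). The other 6 of the top 10 had no protein-coding gene end within 50 kb, and none of the 10 had a MYRF peak. Ranked by knockout replicate 1 alone, the top gained regions with a gene end within 50 kb lay near ALPG, an alkaline phosphatase gene (13.5 and 2.74 in the knockout libraries, chromosome 2, 232420356 to 232422055), SUV39H2, a histone methyltransferase gene (12.03 and 6.94), NFE2L1, a regulator of proteasome genes (11.7 and 5.48), and FOXO3 (11.6 and 4.56), then SLC25A34, PBX4 and the kinase gene ARAF. None of these had a MYRF peak either.

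Genes near lost regions did not gather in any of the 16 lists. The lowest adjusted p of the exact tests was 0.27, shared by epithelial factors (7 of 22 genes, unadjusted p = 0.021), the basal-like program (5 of 15), the unfolded protein response (5 of 17) and N-glycosylation (1 of 38); by unadjusted p, 2 lists were under 0.05. Chaperones had 2 of 32 genes, ER-associated degradation 0 of 19, translocation 5 of 24 and ER-to-Golgi transport 7 of 37. Genes near gained regions included 12 of the 26 glycoprotein genes (odds ratio 10.2, 4.68 to 22.02, exact test, adjusted p = 2.9e-06), among them EPCAM, an epithelial adhesion molecule (6.29 and 4.11), CDH1 (5.80 and 7.30), CEACAM1, MUC5AC and MET. The mixed groupings gave 6, 7, 3 and 6 of the 26 genes, the highest with an exact test adjusted p of 0.025. This call ended with assignment within 5 kb, with stricter H3K27ac peaks, and with regions as units (exact test, adjusted p = 0.14). For gained regions, all other lists had an adjusted p of 0.18 or above. Near lost regions lay 4 of the 26 glycoprotein genes, CDH1 and MET again among them.

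Acetylation was not lost more often at regions with MYRF than at those without, though more often than mixed groupings of the libraries gave. The few MYRF sites that changed did so mostly towards loss. Of 2600 control regions with MYRF, 27 (1.04%) were lost, against 7.10% of regions without MYRF. Weak regions drop out of lists more often, and within deciles of strength the odds ratio was 0.68 (0.46 to 1.01, exact p = 0.053). Regions with FOS were lost less often (423 of 20326, odds ratio 0.46, 0.42 to 0.51, exact p = 5.0e-54) and also gained less often (0.32, 0.28 to 0.37, exact p = 1.1e-66). At MYRF sites the odds ratio of gain was 0.10 (0.032 to 0.31, exact p = 7.7e-10), with 3 of 2514 regions gained. In the mixed groupings the MYRF odds ratio was 0.38, 0.38, 0.23 and 0.29 (9, 9, 10 and 8 regions with MYRF). All were lower than the 0.68 of loss and higher than the 0.10 of gain. Groupings unrelated to the knockout thus also gave values under 1, so the 0.68 does not show that regions with MYRF were spared. The FOS odds ratio in them was 0.80, 0.19, 0.80 and 0.19, so some of these groupings gave FOS values further under 1 than those of loss and gain. Without a control library in turn, the MYRF loss value was 0.40 or 0.41 and the MYRF gain value 0.27 or 0.076, and without control replicate 1 the FOS loss value was 0.20 and the FOS gain value 0.68. Unstratified values were 0.14 for MYRF loss, 0.22 for FOS loss, 0.030 for MYRF gain and 0.20 for FOS gain. With stricter H3K27ac peaks FOS loss was 0.71 and FOS gain 0.56, and in 500 bp bins MYRF gain was 0.20. The call on MYRF loss depended on the setting, since in 500 bp bins the odds ratio was 0.655 (0.52 to 0.82, exact p = 8.8e-05).

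Counted per MYRF peak, 32 sites were lost and 4 gained, whereas FOS sites without MYRF had 310 lost and 154 gained (odds ratio 3.97, 1.38 to 11.4, Fisher's exact p = 0.0049, adjusted p = 0.0097 over 18 tests chosen after the counts were seen). The GRAMD1B site, the best ranked MYRF peak, was among the lost ones. Its control H3K27ac peaks, with 7.23 and 9.90 fold enrichment, had no counterpart in either knockout library, in which the nearest peaks began at 123590093 and 123589877. Other lost MYRF regions of high rank in control replicate 1 lay inside MAP3K20, a stress kinase gene (6.88 and 3.34), ERGIC1, a protein of the ER-Golgi intermediate compartment (6.32 and 3.42), and KBTBD11 (5.95 and 2.95), and near PRKAG2, a subunit of AMP-activated kinase (5.94 and 4.45). Another 5 of the top 10 had no protein-coding gene end within 50 kb. Chosen after their values were seen, lost sites inside TBCE, CAMK2A and FGD5 and near RASSF10 and FSCN1, an actin-bundling gene, followed, and 3 of the 4 gained sites lay near CACHD1, the homeobox gene EN1 and GLI2, a hedgehog pathway factor. Of the 32 lost sites, 12 belonged to the top quintile of MYRF peaks, 13 had FOS and 15 were also HPAF2 sites. Mixed groupings of the libraries gave 22 against 6 and 22 against 7 MYRF sites, where FOS sites without MYRF had 307 against 92 and 535 against 87. The counts depended on which libraries were used: without control replicate 1 they were 55 lost and 28 gained MYRF sites (469 and 788 FOS sites), without control replicate 2 they were 53 and 13 (984 and 282), without knockout replicate 1 they were 65 and 20 (749 and 481) and without knockout replicate 2 they were 94 and 13 (1049 and 470). Without control replicate 2 the odds ratio was 1.17 (0.63 to 2.17, exact p = 0.76) and without knockout replicate 1 it was 2.09 (1.25 to 3.49). With stricter MYRF and FOS peaks it was 12.6 (1.64 to 96.9, 19 MYRF sites lost and 1 gained), and for MYRF peaks also found in HPAF2 it was 3.73 (0.84 to 16.5, exact p = 0.069). HPAF2 MYRF sites with no CFPAC1 MYRF peak leaned towards loss too, with 14 lost and 4 gained. Their odds ratio against the same FOS sites was 1.74 (0.56 to 5.37, exact p = 0.45).

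**Figure D2:**
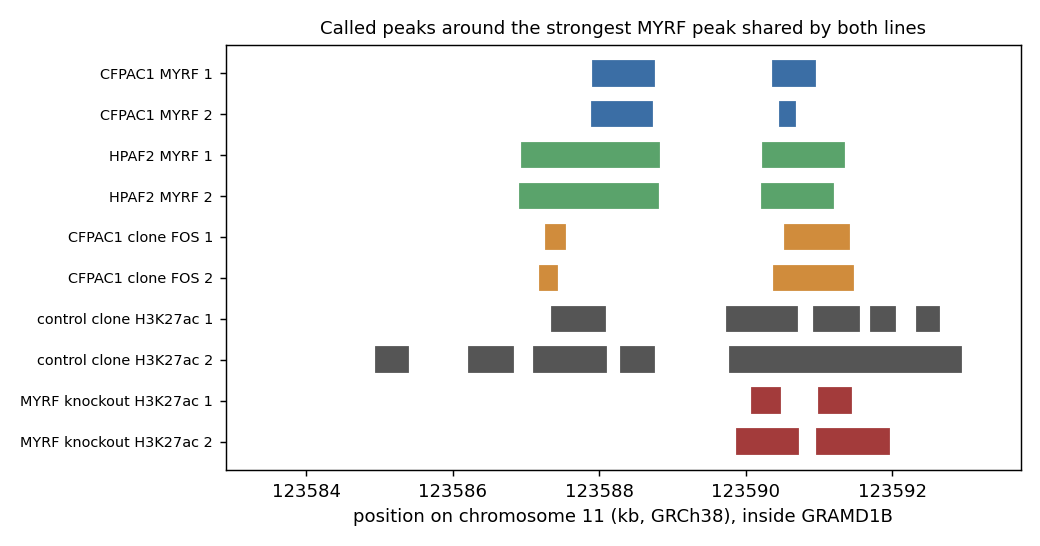
Called peaks of all 10 libraries (1 line per library) along chromosome 11 around the best ranked shared MYRF peak inside GRAMD1B, in kb of GRCh38. H3K27ac peaks of the control clone overlap the MYRF peak at 123587901 to 123588753 in both libraries and those of the knockout clone in neither.

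The mean acetylated stretch around MYRF sites was shorter in the knockout clone, most so at the strongest sites. The mean around FOS sites without MYRF was shorter as well. Over the whole genome, H3K27ac peaks covered 100.5 and 95.2 Mb in the control and 87.9 and 92.9 Mb in the knockout libraries. Within 1 kb either side of the summit, H3K27ac peaks covered a mean of 1486 and 1449 bp in the control libraries and 1377 and 1419 bp in the knockout libraries (mean of means 1467 ± 26.5 and 1398 ± 29.4, SD, n = 2 libraries each). At the top quintile of MYRF sites the means were 1589 ± 12.4 and 1462 ± 22.3 bp, and at the lowest quintile 1409 ± 34.0 and 1372 ± 30.8 bp. At FOS sites without MYRF they were 1082 ± 82.1 and 1026 ± 38.7 bp. There the libraries of the clones overlapped, with 1140 and 1024 bp in control and 998 and 1053 bp in knockout. Coverage was lower in both knockout than in both control libraries at 18.1% of MYRF sites (16.7 to 19.6) and higher at 6.48% (5.63 to 7.45). From the lowest to the top quintile, the share with lower coverage was 14.2%, 15.4%, 15.6%, 19.9% and 25.6%, and the share with higher coverage was 6.99%, 4.65%, 7.17%, 8.41% and 5.19%. The top quintile differed from the lowest with an odds ratio of 2.08 (1.54 to 2.83, Fisher's exact test, adjusted p = 1.2e-05). FOS sites without MYRF had lower coverage at 16.5% and higher at 7.47%, the top quintile of these at 15.6% and 8.97%, and HPAF2 sites with no CFPAC1 MYRF peak at 12.7% and 4.61%. Against FOS sites, MYRF sites as a whole had an odds ratio of 1.12 (exact test, adjusted p = 0.043), which was 0.78 without control replicate 2 and did not pass without either knockout library. A fall of more than 500 bp occurred at 37 MYRF sites, 18 of them in the top quintile, and a rise of that size at 1. Chosen after their values were seen, sites inside STK32B, USP3 and MAP3K20 and near PTGIS, the prostacyclin synthase gene, were among those with the longest falls, and the rise lay inside ITGAM. The USP3 site, for example, had 1656 and 1985 bp covered in the control and 436 and 489 bp in the knockout libraries.

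**Figure D3:**
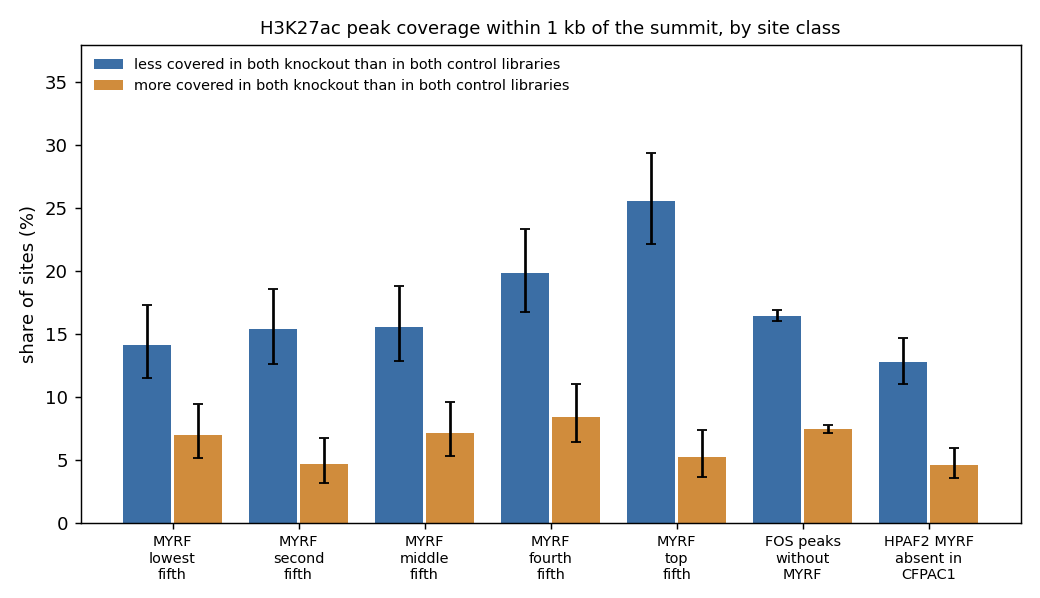
Share of sites (%) with less or more H3K27ac peak coverage within 1 kb of the summit in both knockout than in both control libraries, for 5 strength classes of CFPAC1 MYRF sites, FOS sites without MYRF and HPAF2 MYRF sites absent in CFPAC1. Bars are shares and lines their 95% Wilson intervals; the lower share is 14.2% in the weakest and 25.6% in the strongest MYRF class.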

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

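The alternatives were fixed before the data were examined, except gene spans, regions as units and all those of lost against gained sites and of coverage, which were added after the results were seen. Of 140 alternatives over 23 results, 84 were labelled the same. For these a test kept its direction and side of the threshold, a share stayed in the main interval, or a count stayed within a fixed factor. Shares or counts moved further in 44. Of the other tests, 7 passed the threshold only under the alternative, 4 no longer passed it and 1 reversed. For gene lists these labels compare the number of passing lists, not which lists passed. The transcript start alternative and the 3 motif alternatives were not run, since no transcripts or genome were used here. Peak lists without read counts leave depth unknown, so absence of a peak cannot be told from low depth.

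Replicate overlap of MYRF peaks was 53.9% in CFPAC1 and 73.1% in HPAF2 with 50% reciprocal overlap, 55.7% and 75.5% with summits within 200 bp, and 71.8% and 83.1% with a -log10 q of at least 10; the first 2 rules are narrower by construction, and for the last the cause was not tested. The share of MYRF peaks in H3K27ac (control 1 and 2, knockout 1 and 2) was 86.8%, 86.4%, 84.2% and 85.0% within 500 bp of the summit, a wider rule, 93.1%, 92.5%, 88.3% and 89.7% for stricter MYRF peaks, where the cause was not tested, and 78.7%, 76.2%, 72.4% and 74.6% with stricter, hence fewer, H3K27ac peaks. Cross-line overlap stayed enriched, from 51.0 to 138, as did MYRF with FOS, from 4.47 to 9.96, and MYRF at gene ends, from 1.14 to 1.58.

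Lost regions numbered 2099 with stricter H3K27ac peaks, 9745 as 500 bp bins and 1664 when joined across 1 kb, and gained regions 648, 3795 and 966. Leaving out a library gave 8713 to 18729 lost and 4372 to 13296 gained, with more gained than lost without either knockout library, since fewer lists must then hold or lack a peak. All these follow from the construction of the unit.

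The odds ratio of loss at MYRF sites passed the threshold, still under 1, without strength strata (0.137), in 500 bp bins (0.655), and with each library left out (0.398 to 0.745). In simulated data without any effect the unstratified median was 0.197, so omitting strength can lower the value that far. The observed 0.137 was lower still, and those runs drew loss for each region independently, so they do not settle its cause. For the others the cause was not tested. With replicate number as a block, scored within same-numbered pairs, it was 0.465 (0.396 to 0.547, exact p = 4.0e-24), which also passed the threshold. The correlation of replicate differences in peak presence between the clones was -0.0496 over regions. This gave no sign that same-numbered libraries were paired, but it cannot show how they were prepared. The block gave 0.417 for loss at FOS, 0.374 for gain at FOS and 0.144 for gain at MYRF sites and changed no call among these. Gain at FOS sites was 0.203 without strata, loss at FOS sites 0.707 with stricter H3K27ac peaks and gain at MYRF sites 0.196 in 500 bp bins.

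Lists past the threshold numbered 0 in CFPAC1 with assignment within 5 kb, 2 with stricter peaks and 2 with regions as units (4 before); in HPAF2 4 within 5 kb, 0 with stricter peaks and 3 with regions as units (5 before), with the classical program and ribosomal proteins among the 4 and the classical program among the 3, none of them among the 5; for FOS 4 with assignment within 5 kb, 4 against all protein-coding genes, 5 with stricter peaks and 3 with regions as units (8 before). For gained regions it was 0 within 5 kb, 0 with stricter H3K27ac peaks and 0 with regions as units (1 before), and for lost regions 0 throughout. Odds ratios of the lists that passed ranged over the alternatives, in CFPAC1 MYRF, from 2.92 to 19.1 for glycoproteins, 3.86 to 10.9 for the basal-like program, 2.17 to 13.1 for AP-1 and 1.88 to 5.40 for epithelial factors, and in HPAF2 MYRF from 4.12 to 11.8, 2.59 to 5.70, 3.22 to 9.32 and 2.27 to 7.78, and from 0 to 11.5 for myelin genes. Assignment within 5 kb and stricter peaks leave fewer genes with a peak; otherwise the cause was not tested.

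Lost against gained at MYRF sites, against FOS sites, gave 3.73 for MYRF peaks also in HPAF2, no longer past the threshold with 17 changed sites, 12.6 with stricter MYRF and FOS peaks, where 1 gained MYRF site was left, and 1.17 to 3.30 with a library left out, the lowest without control replicate 2. Lower coverage at MYRF against FOS sites ranged from 0.782, a reversal without control replicate 2, to 1.12 with a library left out. The cause was not tested. The top against the lowest quintile of MYRF sites kept its call, at 1.76 to 2.25.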

Other observations

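The tests by matched draws, by leaving out single libraries and by MYRF strength classes were chosen after the result was seen, whereas the comparison of breadth, that of weak with strong MYRF peaks with FOS and the odds ratio within strength deciles were planned before their values, though the bound for the last was written after. A set of 367 MYRF sites, 13.1% of the 2793 in CFPAC1, had no H3K27ac peak in any of the 4 libraries. The site inside PDE9A was the strongest of these by joint rank, at 35.7 and 32.7 in CFPAC1 and 81.0 and 86.8 in HPAF2. It was followed by sites inside the glutamate receptor gene GRIN2A (33.7 and 28.6, 34.2 and 34.9), inside DOCK1, inside MTHFD1L and near WSB1, and by a site 333 bp from SSR2. Apart from PDE9A and SSR2, these genes were chosen after their values were seen.

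Sites of MYRF lost acetylation more often than they gained it, 32 against 4 (55 against 28 without control replicate 1, 53 against 13 without control replicate 2, 65 against 20 without knockout replicate 1 and 94 against 13 without knockout replicate 2), with a gradient along MYRF strength in covered length. Fewer peaks in the knockout lists as a whole would give the same skew at other peaks of equal strength. With H3K27ac peaks as units, those at MYRF sites had 32 lost and 3 gained, a lost share of 91.4%. In 10000 matched draws the median share was 61.1% (50 to 72.5, the central 95%). The permutation p of 0.0001 is the smallest the draws can give. The draws had medians of 38 lost and 24 gained peaks. Peaks at MYRF sites were thus not lost more often than matched peaks, and the skew came from fewer gains. Wider acetylation at strong sites was weighed within deciles of covered length, where the odds ratio of lower coverage, top against lowest quintile, was 1.61 (1.16 to 2.24, exact p = 0.0053), so width alone is argued against. A dependence of acetylation on MYRF itself is a candidate explanation, since the strongest sites lost coverage more often, with an odds ratio of 2.08. That comparison was chosen after the result was seen, and it cannot decide the cause. HPAF2 MYRF sites with no CFPAC1 MYRF peak also leaned towards loss, with 14 lost and 4 gained. Their coverage was lower at 12.7% and higher at 4.61%. A contribution of control replicate 2 alone cannot be told apart, because without it the odds ratio against FOS sites was 1.17 (0.63 to 2.17). The lost share was then 80.3% at MYRF sites and 77.7% at FOS sites without MYRF. Without control replicate 1 these shares were 66.3% and 37.3%, so the FOS share depended strongly on the control library left out. The 1.17 thus also reflects the FOS sites and does not trace the skew to control replicate 2. A difference between the clones other than MYRF stays open and untested.

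The coincidence of MYRF with FOS could come from unspecific recovery of open chromatin in weak MYRF peaks, which would make FOS more frequent among them. The share with FOS was instead lower in the lowest quintile of MYRF peaks, with a difference of -6.86 percentage points (62.9% against 69.8%, odds ratio 0.73, 0.57 to 0.94, Fisher's exact p = 0.016). The separate intervals of the shares overlap, and the interval of the odds ratio was taken as the measure after the values were seen. The lowest quintile also overlapped H3K27ac less often, at 78.7% and 76.7% in the control libraries against 92.8% and 93.2% in the top quintile. The shares with FOS were not compared at equal acetylation, so this comparison cannot decide whether weak peaks were unspecific. H3K27ac strength alone would leave no association within strength deciles, where the odds ratio was 5.89 (5.33 to 6.50). Chromatin accessibility as such was not measured and stays open, and so does a biological partnership of the factors, which was not tested.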
